A study of Homo sapiens with 8 samples.

How the data were processed

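Gene expression was profiled in human liver cell cultures with Illumina HumanHT-12 v4 bead arrays, which carry 1 bead-bound oligonucleotide probe per transcript region and read it in 1 colour. The 8 arrays fall, by the group characteristic in the labels, into 3 arrays of monolayer culture (2D), 3 of static culture in a scaffold (static 3D) and 2 of the same scaffold under perfusion (perfused 3D). Per the labels' protocols, total RNA was amplified with the TotalPrep kit, labelled with biotin and stained with streptavidin-Cy3. The labels disagree about the cells: their characteristics name HepG2, a human hepatocellular carcinoma line, whereas the source name and the design text speak of hepatocytes from several donors. They do not say which donor, or which separate culture, an array came from, so donor could not enter any model, and p-values measure only the spread between these samples, which may be technical. The design text speaks of 3 perfused cultures, of which 2 arrays were analysed here.

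Per the file headers, the authors deposited for each array the mean bead intensity of 47323 probes and, beside it, the detection p-value of each probe. Those p-values moved in steps of 1/770, a rank among negative-control beads. The deposited intensities were all above 0 and had not been normalised between arrays (medians 279 to 386 units). The scanner software and its settings are not given in the sources used here. The authors also deposited a table of processed values on a log2 scale. Each of its columns ranked the probes exactly as the intensities of the same array did (Spearman correlation 1), with a slope of 1.03 to 1.05 on log2 intensity among bright probes, values down to -4.69, and medians of 7.46 to 7.64. The base 2 and the subtraction of an offset were read from the values. The authors' normalisation is not given in the sources used here, and their table served only as an alternative.

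From the intensities, background was corrected with limma 3.58.1 in R 4.3.3 by the normexp model, whose negative-control mean and spread were inferred from the detection p-values, with an offset of 16. Quantile normalisation between arrays and log2 transformation followed. Of the 47323 probes, 30113 carry 1 gene symbol in the platform annotation, 8 carry several and 17202 are unlisted there and stayed unnamed here. A probe was kept when its detection p lay under 0.05 on at least 2 arrays, which left 18556 probes, 14115 of them with 1 gene symbol. Where a gene had several kept probes (2506 genes), the probe with the highest mean over all 8 arrays stood for it, which gave 11031 genes. The 4441 kept probes without a single symbol were tested only in an alternative, beside the genes. Between 29.7% and 34.3% of probes were detected per array. On arrays the number of arrays limits the precision: the median standard error of a log2 fold change was 0.29 for static 3D against 2D and 0.33 for both comparisons with perfused 3D. For a gene not detected on any array of a group, the fold is given as "at least", with each undetected array set to the higher of its own value and the lowest level of any detected probe on that array.

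All 8 arrays entered a single linear model with a mean per group and no covariate (lmFit, then eBayes with an intensity trend, 5 residual and 8.45 total degrees of freedom). The contrasts were static 3D against 2D, perfused 3D against 2D and perfused against static 3D, each two-sided, with Benjamini-Hochberg adjustment over the 11031 genes at 0.05. Gene lists were compared with all other genes by camera (limma) with a preset inter-gene correlation of 0.01, adjusted over the 35 lists with at least 5 members measured, out of 36 written. Camera with an estimated correlation and fry, a directional test of a list on its own, were the alternatives. The lists cover liver functions, metabolism, stress responses and markers of other liver cell types. The groups, contrasts, lists, tests and rule for named genes were set before the data were examined. By that rule the text could name, per contrast, up to 6 called genes per direction (3 with the smallest p where under 3 were called), the 3 members with the smallest p of each list that passed and of 4 standing lists, and 9 fixed genes, of which 7 were measured and the others were not analysed here. Genes whose level can reveal a donor's sex or genotype were never named.

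The arrays lie on 2 chips. Chip 1 holds static 3D replicate 1 and both perfused arrays, and chip 2 holds the other 5. Because static 3D alone is on both, a model with chip as a fixed block compares static 3D with 2D on chip 2 only, and perfused with static 3D on chip 1, 2 arrays against 1. Those values are called within-chip values. For static 3D against 2D they leave out static 3D replicate 1, so they nearly repeat the fit without that array. Perfused 3D and 2D share no chip, so their value with chip as a block is the sum of the 2 within-chip differences through static 3D replicate 1. Replicate numbers only name the arrays. Other alternatives were the background step, the normalisation, the filter on dim probes, the probe rule, array weights, the variance model, chip as a random block (statmod 1.5.0), the arrays of only 2 groups, and each array left out in turn. A further 3 were added after the data were seen: leaving out 2D replicate 1 and static 3D replicate 1 together, a residual principal component as a covariate, and testing the unnamed probes beside the genes.

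The steps were tested on data simulated from the gene means and spreads of the main fit. In 10 draws with 200 of 11031 genes changed, limma recovered 86.6% of 4-fold changes for static 3D against 2D, 75.4% for perfused 3D against 2D and 77.4% for perfused against static 3D. At 2-fold it recovered 17.2%, 8% and 6.8%, and the share of false calls was 4.48%, 5.97% and 5.68%. The noise of each gene was drawn independently there, so these rates need not hold for correlated genes. A second simulation, chosen after the data were seen, drew 100 data sets with no group effect. Their genes stayed correlated as in the model's residuals. Limma called a median of 0 genes in each contrast, with 95th percentiles of 1530, 0 and 53 genes in the same order. Camera with the preset correlation then called a median of 13, 14 and 13 lists in the 3 contrasts, so each list that passes it is given below with its estimated-correlation p, and with how often the 100 data sets gave a median as far from 0. These data sets let likeness between arrays of different groups fall freely, so any donors shared between groups are not kept balanced in them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.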

Results

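Liver cell cultures were grown for 5 days as a monolayer (2D, 3 arrays), in a polycarbonate scaffold with micropores kept in wells (static 3D, 3 arrays), or in the same kind of scaffold inside a bioreactor through which a pump drove medium (perfused 3D, 2 arrays). RNA of each sample was hybridised to 1 bead array, and 11031 genes were compared on the log2 scale after background correction and quantile normalisation. The albumin gene ALB lay between 15.6 and 15.8 on all 8 arrays, among the 6 highest probes of each, where quantile normalisation largely fixes the level. The monolayers were started with 0.25 times as many cells as the scaffolds, so format and seeded number are changed together there.

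Arrays differed in ways their groups do not explain. Genes of Kupffer cells and other macrophages, the resident immune cells of liver, were lower on average on 2D replicate 1 and static 3D replicate 1, with 8 and 7 of 22 detected against 18 or more on each other array. There the list mean was 6.84 and 7.02, against 8.71 to 10.1 on the other arrays. Not all members were low: CD68, a lysosomal protein of macrophages, lay at 11.4 and 12.1 there and between 11.26 and 13.01 elsewhere. The complement gene C1QB lay at 5.45 and 5.44 on these arrays and between 10.9 and 12.8 elsewhere, and the collagen gene COL1A1 at 6.35 and 6.38 against 10.9 to 12.2. Genes of the dividing cell went the other way, with a mean of 10.1 on 2D replicate 1 and 9.82 on static 3D replicate 1 and 7.31 to 7.89 elsewhere. The replication enzyme gene TOP2A lay at 10.7 and 10.6 on them, against at most 7.90 on any other array. Across genes, arrays of the same group correlated with a median r of 0.913 over 7 pairs and arrays of different groups with 0.945 over 21 pairs. The array nearest to another was of a different group in 7 of 8 cases, with r of 0.921 between 2D replicate 1 and static 3D replicate 1, 0.976 between perfused replicate 1 and both 2D replicate 2 and static 3D replicate 2, and 0.968 between 2D replicate 3 and perfused replicate 2. The exception was static 3D replicate 3, nearest to static 3D replicate 2 at 0.969. The labels tie no array to a donor, so such likeness across groups stays in the residual spread of the model used below. The first principal component of the residuals held 53.8% of the variance, with 2D replicate 1 at 0.63 and static 3D replicate 1 at 0.49 and the other arrays between -0.40 and 0.13.

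**Figure D1:**
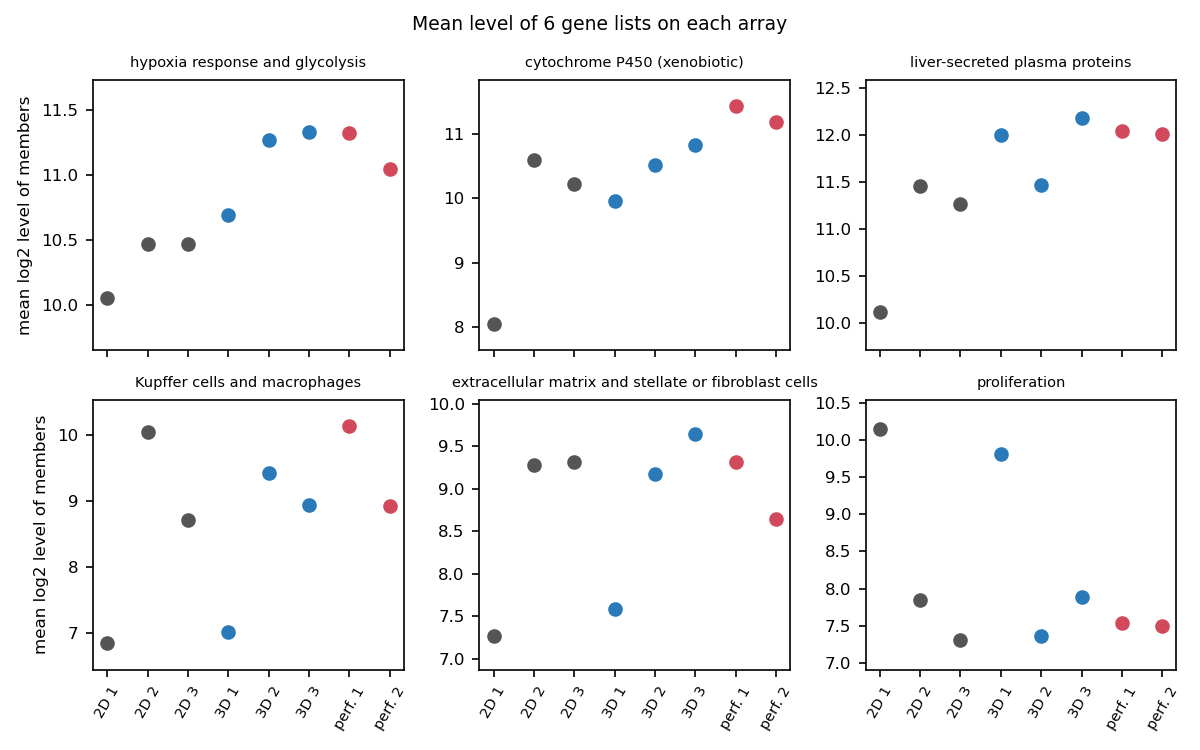
Mean normalised log2 level of the members of 6 gene lists (vertical axes) on each of the 8 arrays (horizontal axes; grey 2D, blue static 3D, red perfused 3D, labelled perf.). Macrophage and matrix genes are lowest and proliferation genes highest on 2D replicate 1 and static 3D replicate 1, and the hypoxia list lies at 10.1 to 10.5 on the 2D arrays and at 10.7 to 11.3 on the others.

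Static 3D was compared with 2D to see what the scaffold changes without flow. By camera's preset test, though not with an estimated correlation, genes of hypoxia response and glycolysis rose in static 3D, with a median log2 fold change of 0.68 and 30 of 33 members higher. Their mean was 11.10 ± 0.35 (SD, n = 3) in static 3D and 10.33 ± 0.24 (SD, n = 3) in 2D, and no static 3D array fell into the 2D range. PFKFB4, an enzyme that sets the rate of glycolysis, was higher by 2.00 (SE 0.26), the stress-responsive gene NDRG1 by 1.69 (SE 0.30) and the glycolytic enzyme gene ENO2 by 2.22 (SE 0.42), in all cases with no overlap between the 3 arrays of each group. Adjusted over the list alone, 9 of the 33 genes passed, while 0 passed over all genes. The list had an adjusted p of 9.4e-15 with camera's preset correlation and an adjusted p = 0.369 with an estimated correlation, and 0 of the 100 data sets simulated without an effect gave a median as far from 0. The median was 0.71 within chips and 0.69 without 2D replicate 1 and static 3D replicate 1, and it ran from 0.46 to 0.81 with each array left out in turn.

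Genes for proteins that hepatocytes secrete into plasma were higher in static 3D too, by the preset test alone. Coagulation and complement genes rose by a median of 1.11 (32 of 33 members higher), acute-phase genes by 0.91 (23 of 25) and other secreted plasma proteins by 0.76 (26 of 28). The lipoprotein genes APOA4 and APOC3 differed by 3.55 (SE 0.65) and 1.92 (SE 0.43), the iron carrier gene TF by 1.65 (SE 0.43), the plasmin inhibitor gene SERPINF2 by 3.28 (SE 0.77) and antithrombin, SERPINC1, by 1.32 (SE 0.35), each with all 3 static 3D arrays above all 3 of 2D. Haptoglobin, HP, differed by 2.58 (SE 0.76) with overlapping arrays. Adjusted over the list alone, 3 plasma protein genes passed and none of the coagulation or acute-phase genes did. All 3 lists had an adjusted p = 0.434 with an estimated correlation, and 12, 18 and 7 of 100 simulated data sets gave medians as far from 0. The within-chip medians were 1.23, 1.19 and 0.80. The size depended on 2D replicate 1, whose plasma protein mean was 10.1 against 11.3 and 11.5 on the other 2D arrays. Without it the medians were 0.50, 0.40 and 0.47, still past camera's preset test. Without both 2D replicate 1 and static 3D replicate 1 they were 0.51, 0.78 and 0.34, also past it, so the acute-phase median stayed near its first value there.

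Other liver lists rose by smaller amounts in static 3D, again by the preset test alone. Hepatocyte transporters had a median of 0.59, gluconeogenesis and glycogen genes 0.53, cytochrome P450 genes of drug metabolism 0.52, liver transcription factors 0.42, other phase I enzymes 0.34, immediate early genes 0.33, urea cycle and amino acid genes 0.20 and genes of the unfolded protein response 0.20 (-0.02 with median scaling). Examples were the glycerol channel AQP9 at 1.22 (SE 0.37), BHMT, which remethylates homocysteine, at 1.57 (SE 0.26), the glyoxylate enzyme AGXT at 2.18 (SE 0.52), the transcription factors ATF5 at 1.16 (SE 0.29) and FOXA3 at 1.42 (SE 0.44), and EGR1 at 0.68 (SE 0.27). Within the urea cycle and amino acid list 4 of 35 genes passed when adjusted over the list alone. The P450 genes CYP2C8, CYP2E1 and CYP1A2 differed by 2.54 (SE 0.98), 1.46 (SE 0.83) and 1.83 (SE 1.41) with overlapping arrays, and by 1.33 (SE 0.59), 0.49 (SE 0.58) and -0.06 (SE 0.60) without 2D replicate 1. CYP1A2 was at 2.94 without 2D replicate 2 and at 1.22 without static 3D replicate 3, where CYP2E1 was at 0.83. Genes of oxidative phosphorylation fell by a median of 0.18 (34 of 42 lower, NDUFB3 at -0.50, SE 0.18), NRF2 and oxidative stress genes by 0.33 (15 of 21 lower, thioredoxin TXN at -0.86, SE 0.24) and ribosomal protein genes by 0.15 (26 of 38 lower). With an estimated correlation the adjusted p was 0.434 for oxidative phosphorylation, transcription factors, immediate early genes and gluconeogenesis, 0.507 for transporters and the unfolded protein response, 0.561 for P450 genes and 0.608 for the rest. In the simulation without an effect, medians as far from 0 came up in 2 of 100 data sets for oxidative phosphorylation, 4 for gluconeogenesis, 5 each for transporters and immediate early genes, 6 for the unfolded protein response, 10 for transcription factors, 15 for ribosomal proteins, 18 for NRF2 genes, 29 for other phase I enzymes, 40 for urea cycle genes and 46 for P450 genes. The within-chip medians had the same sign in all of these lists, and 14 of the 15 lists that passed also passed within chips, ribosomal proteins being the exception at -0.12 (adjusted p 0.300). Static 3D replicate 1 does not enter these within-chip differences, so they are no check apart from the fit without that array. Without both 2D replicate 1 and static 3D replicate 1, 8 of the 15 passed. Those that did not were transporters (0.29), transcription factors (0.28), P450 genes (0.30), other phase I enzymes (0.16), gluconeogenesis (0.05), urea cycle genes (-0.06) and ribosomal proteins (0.009). Leaving out 2D replicate 1 ended the calls of P450 genes (0.10), transporters (0.31), transcription factors (0.16), other phase I enzymes (0.09), gluconeogenesis (0.44), urea cycle genes (0.03), the unfolded protein response (0.15) and ribosomal proteins (0.01, with the sign turned). Leaving out static 3D replicate 1 ended that of ribosomal proteins (-0.12), and 2D replicate 2 that of the unfolded protein response (0.18). NRF2 genes no longer passed without 2D replicate 3 (-0.21) or static 3D replicate 2 (-0.12). Leaving out static 3D replicate 3 ended those of other phase I enzymes (0.28) and the unfolded protein response (0.13). Other calls held but moved. P450 genes went to 1.07, other phase I enzymes to 0.54 and urea cycle genes to 0.38 without 2D replicate 2. Immediate early genes went to 0.22 without 2D replicate 1, and ribosomal proteins to -0.24 without 2D replicate 3. Urea cycle genes went to 0.30 and the unfolded protein response to 0.32 without static 3D replicate 2. Without static 3D replicate 1 immediate early genes went to 0.51, gluconeogenesis to 0.34, transcription factors to 0.26 and the unfolded protein response to 0.12. Scaling mattered too, since median scaling lowers the median of all genes by 0.13 here. With it urea cycle genes were at 0.009, immediate early genes at 0.11, gluconeogenesis at 0.31, transcription factors at 0.26, NRF2 genes at -0.55, oxidative phosphorylation at -0.40 and ribosomal proteins at -0.35, all still past the preset test. With the authors' values urea cycle genes were at 0.09, immediate early genes at 0.17 and oxidative phosphorylation at -0.32, and the unfolded protein response no longer passed (0.05). Array weights ended the calls of ribosomal proteins (-0.08), urea cycle genes (0.07) and the unfolded protein response (0.07), and gave 0.41 for plasma proteins, 0.28 for gluconeogenesis and -0.51 for NRF2 genes. Without background correction transporters were at 0.31 and transcription factors at 0.21. Probes detected on all 8 arrays alone ended those of gluconeogenesis (0.46), transporters (0.59), other phase I enzymes (0.31) and the unfolded protein response (0.18), and the mean of all probes of a gene that of the last (0.16).

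No single gene passed the test between static 3D and 2D: limma called 0 of 11031 genes (smallest adjusted p 0.417, for PFKFB4), with 519 genes at an unadjusted p under 0.05 where 552 are due by chance, and camera with an estimated correlation and fry called 0 of 35 lists. The 15 lists of camera with the preset correlation were reached in 35 of the 100 data sets simulated without an effect. Of all genes 10.1% showed no overlap between groups, against 10% by chance. This level and the 552 take the arrays as interchangeable, which the likeness of arrays across groups goes against. These counts therefore do not show that an effect is absent. Outside the lists, the smallest p-values belonged to KISS1R, a peptide receptor gene not detected in 2D and at least 6.37-fold higher in static 3D, and LTB, a lymphotoxin gene, at 1.55 (SE 0.25). In the other direction they belonged to SETD9, not detected in static 3D and at least 1.98-fold higher in 2D, and to UQCC5 at -1.15 (SE 0.25) and PRRG1 at -1.15 (SE 0.26). Vimentin, VIM, a mesenchymal filament gene, differed by -0.44 (SE 0.21), AFP by -0.74 (SE 0.29) and the bile duct keratin KRT7 by -1.09 (SE 0.48), and COL1A1 by 0.37 (SE 1.77). Without 2D replicate 1 KRT7 was at -0.65 and VIM at -0.26, and KRT7 was at -0.64 without static 3D replicate 3. COL1A1 ran from -1.31 without 2D replicate 1 to 2.25 without static 3D replicate 1.

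Perfused 3D was compared with 2D, where scaffold, flow and seeded number change together. Any difference in cell source or donor is mixed in too, since 2D replicate 1 stands apart and neither perfused array does. CYP3A4, the main drug-oxidising cytochrome P450 of adult liver, rose in perfused 3D and was the only gene called. Its log2 level was 9.06 and 9.53 on the perfused arrays (9.29 ± 0.34, SD, n = 2), while it was not detected on any of the other 6 arrays (5.54 to 6.02, below the lowest detected levels of 6.75 to 6.94). The log2 fold change over 2D was 3.45 (SE 0.24, limma adjusted p = 0.00337), at least 5.59-fold. This SE and p-value include the spread of the 6 undetected values, which is background. Only the 2 perfused arrays show the spread of a detected level. A single probe measured CYP3A4. CYP3A7, its fetal paralogue, had a log2 fold change of 2.71 (SE 0.36, adjusted p = 0.283), and POR, the reductase that feeds electrons to P450 enzymes, of 1.62 (SE 0.31), with both perfused arrays above all 2D arrays. Perfused 3D and 2D share no chip. A value with chip as a block therefore adds perfused minus static 3D on chip 1 to static 3D minus 2D on chip 2, and hangs on static 3D replicate 1, the only static array of chip 1. For CYP3A4 it was 3.13 (SE 0.39, adjusted p = 0.371). Without perfused replicate 2 the difference was 3.18 (adjusted p = 0.0503), and over the 22 alternatives that tested the gene the adjusted p ran from 8.1e-04 to 0.371.

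**Figure D2:**
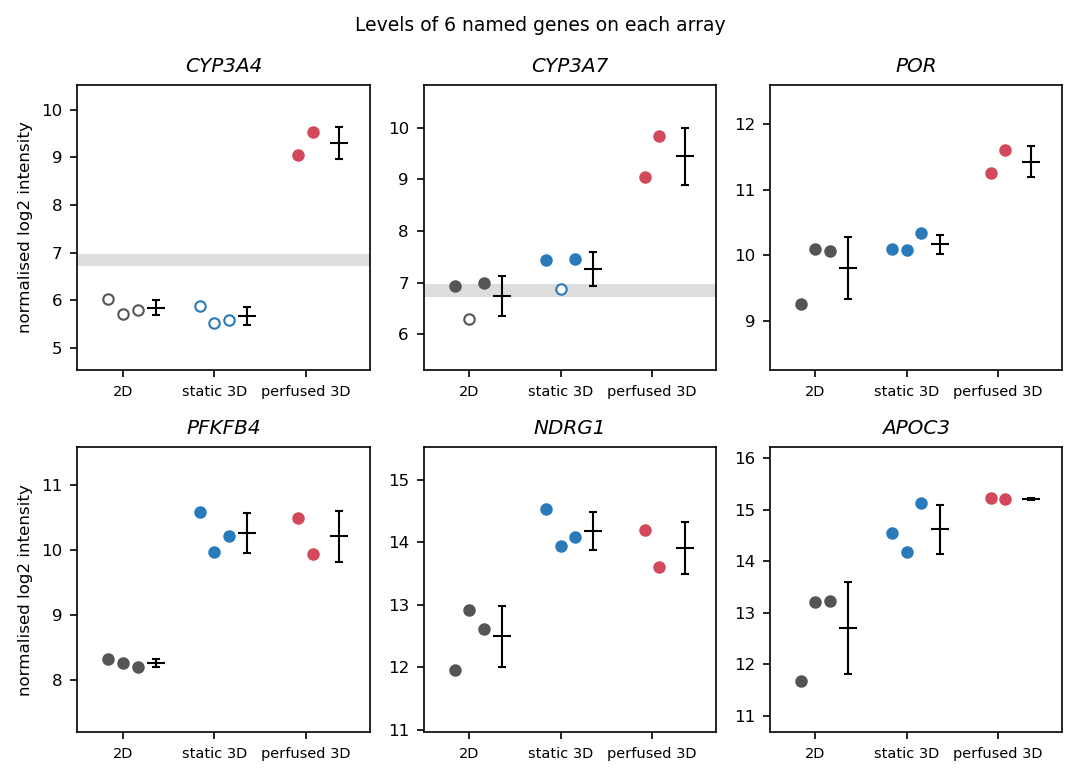
Normalised log2 intensity (vertical axes) of 6 genes on each array, by culture format (horizontal axes). Filled circles are detected and open circles undetected values, bars give mean ± SD (n = 3, 3 and 2), and the grey band spans the lowest detected levels of the 8 arrays. CYP3A4 lies at 9.06 and 9.53 on the perfused arrays and below the band on all others, and PFKFB4 lies at 8.19 to 8.32 in 2D and at 9.93 to 10.6 in both 3D formats.

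Drug metabolism lists rose in perfused 3D over 2D by the preset test, and none passed with an estimated correlation. All 15 measured cytochrome P450 genes were higher (median 1.19), and 3 of them passed when adjusted over the list alone. Other phase I enzymes rose by a median of 0.72 (20 of 24 higher, 1 passing over the list alone), and phase II conjugation enzymes by 0.36 (20 of 25), among them UGT1A1, which conjugates bilirubin, at 1.68 (SE 0.27). CYP1A2 differed by 3.62 (SE 1.57) and the conjugation gene SULT2A1 by 2.51 (SE 1.12), and without 2D replicate 1 by 1.73 (SE 0.66) and 1.26 (SE 0.65). With an estimated correlation the adjusted p was 0.377 for P450 genes, 0.380 for other phase I enzymes and 0.443 for phase II enzymes, and 9, 0 and 10 of 100 simulated data sets gave medians as far from 0. With chip as a block the P450 median was 2.43, the phase I median 1.05 and the phase II median 0.52. Leaving out 2D replicate 1, the array with the lowest P450 mean (8.04 against 9.95 or more on every other array), gave 0.61 for P450 genes, 0.44 for other phase I enzymes and -0.002 for phase II enzymes, whose call also ended without perfused replicate 2 (0.03) and which moved to 0.58 without perfused replicate 1. Array weights gave 0.77 for P450 genes and ended the phase II call (0.16).

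Secreted proteins and hypoxia genes were higher in perfused 3D than in 2D as well, by the preset test alone. Plasma proteins rose by a median of 0.93 (27 of 28 higher), coagulation and complement genes by 1.12 (30 of 33), acute-phase genes by 0.96 (24 of 25) and hypoxia and glycolysis genes by 0.67 (30 of 33), with 2, 1, 0 and 10 genes passing over the list alone. APOC3 differed by 2.51 (SE 0.48), SERPINC1 by 1.93 (SE 0.39), the iron-binding gene LCN2 by 1.71 (SE 0.40), PFKFB4 by 1.95 (SE 0.29) and NDRG1 by 1.41 (SE 0.33), with no overlap between groups. Without perfused replicate 2 LCN2 was at 0.96. The adjusted p with an estimated correlation was 0.377 for plasma proteins and hypoxia genes and 0.384 for coagulation and acute-phase genes. Medians as far from 0 came up in 1, 11, 5 and 0 of 100 simulated data sets for plasma, coagulation, acute-phase and hypoxia genes. With chip as a block the 4 medians were 1.00, 1.48, 1.51 and 1.24. Without 2D replicate 1 the first 3 were 0.46, 0.31 and 0.28, and without that array and static 3D replicate 1 the hypoxia median was 0.52. With array weights coagulation genes were at 0.62 and acute-phase genes at 0.59, and without background correction coagulation genes were at 0.71.

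Metabolic lists of hepatocytes rose in perfused 3D over 2D by the preset test alone. Medians were 0.62 for urea cycle and amino acid genes (30 of 35 higher), 0.66 for gluconeogenesis and glycogen, 0.45 for transporters, 0.43 for lipogenesis, 0.41 for cholesterol synthesis, 0.40 for bile acid synthesis, 0.39 for fatty acid oxidation and PPARA targets, 0.57 for metallothioneins and 0.32 for liver transcription factors. CPS1, the first enzyme of the urea cycle, differed by 2.03 (SE 0.59), BHMT by 1.69 (SE 0.29), AQP9 by 2.32 (SE 0.42), the lipid regulator CREB3L3 by 2.39 (SE 0.72), the fatty acid desaturase FADS2 by 1.46 (SE 0.39) and CYP8B1, a bile acid hydroxylase, by 2.21 (SE 0.95), or 1.06 (SE 0.38) without 2D replicate 1. The adjusted p with an estimated correlation was 0.377 for bile acid synthesis and gluconeogenesis, 0.380 for the urea cycle, 0.384 for fatty acid oxidation and transporters, 0.443 for lipogenesis and transcription factors, 0.464 for metallothioneins and 0.469 for cholesterol synthesis. Simulated medians as far from 0 came up in 0 of 100 data sets for the urea cycle, 1 for gluconeogenesis, 6 for lipogenesis, 8 each for fatty acid oxidation and metallothioneins, 9 for bile acid synthesis, 10 for transporters, 11 for cholesterol synthesis and 12 for transcription factors. With chip as a block the lists of fatty acid oxidation (0.49) and metallothioneins (0.47) still passed, while others did not. Those were the urea cycle (0.16), gluconeogenesis (0.05), transporters (0.22), bile acid synthesis (0.15), lipogenesis (0.40), transcription factors (0.27) and cholesterol synthesis (-0.04). Leaving out 2D replicate 1 lowered the urea cycle to 0.39, fatty acid oxidation to 0.23, gluconeogenesis to 0.36 and transporters to 0.14, and ended the calls of metallothioneins (0.02), cholesterol synthesis (0.19) and transcription factors (0.09). Without perfused replicate 2 the calls of bile acid synthesis (0.31), cholesterol synthesis (0.08) and lipogenesis (0.18) ended, and without 2D replicate 2 those of cholesterol synthesis (0.28) and lipogenesis (0.42). Without 2D replicate 3 that of transcription factors ended (0.29), as it did without perfused replicate 1 (0.26). Without perfused replicate 1 bile acid synthesis moved to 0.62, cholesterol synthesis to 0.65 and gluconeogenesis to 0.41, without 2D replicate 3 lipogenesis moved to 0.69, and without 2D replicate 2 transcription factors moved to 0.51. Interferon response genes rose by a median of 0.25 (23 of 30 higher, with the antiviral nuclease ISG20 at 0.75, SE 0.30), with an adjusted p = 0.464 with an estimated correlation and 0.27 with chip as a block, where they did not pass, and 25 of 100 simulated data sets gave a median as far from 0. That call ended without 2D replicate 1 (0.05), 2D replicate 2 (0.24) or perfused replicate 2 (0.24), and the median was 0.55 without 2D replicate 3. Without background correction the urea cycle was at 0.35, gluconeogenesis at 0.35, lipogenesis at 0.21 and fatty acid oxidation at 0.25, all still passing. Array weights, which count 2D replicate 1 for less, ended the calls of interferon response genes (0.04), metallothioneins (0.12) and cholesterol synthesis (0.19). The call of transcription factors ended with the mean of all probes of a gene (0.25) and with chip as a random block (0.32).

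Ribosomal protein genes fell in perfused 3D against 2D by the preset test, by a median of 0.34 with 32 of 38 lower, for example RPL23 at -1.15 (SE 0.40). No simulated data set of 100 gave a median as far from 0, the adjusted p with an estimated correlation was 0.380, and the median with chip as a block was -0.15 and did not pass. Without 2D replicate 1 the median over both chips was -0.22. Oxidative phosphorylation fell by a median of 0.12 (30 of 42 lower, ATP5F1C at -1.29, SE 0.45), with an adjusted p = 0.384 with an estimated correlation and 7 of 100 simulated medians as far from 0. It did not pass with chip as a block (-0.07), without 2D replicate 3 (-0.08) or without perfused replicate 1 (-0.04). The dedifferentiation list fell by a median of 0.14 (19 of 27 lower, KRT7 at -2.05, SE 0.54, ANXA3 at -1.70, SE 0.46), with an adjusted p = 0.443 with an estimated correlation, and 39 of 100 simulated data sets gave a median as far from 0. Its sign turned with chip as a block (0.11), and its call ended with cyclic loess (-0.07), no filter (-0.09), chip as a random block (-0.07) and a residual component (-0.14). Its call also ended without 2D replicate 3 (-0.10), without static 3D replicate 1 (-0.14) and without perfused replicate 2 (-0.07). Proliferation genes fell by a median of 0.84, with all 28 lower, and macrophage genes rose by 0.93, with all 22 higher, with adjusted p-values of 0.522 and 0.543 with an estimated correlation and 48 and 37 of 100 simulated medians as far from 0. Both lists follow the arrays that stand apart: without 2D replicate 1 the medians were -0.08 and 0.24, and neither passed, nor did macrophage genes without perfused replicate 1 (0.28). The macrophage median was 1.64 without 2D replicate 2 and 1.51 without perfused replicate 2, and the proliferation median -1.42 without 2D replicate 3 and -0.25 with array weights, where it did not pass. With chip as a block they were -3.05 and 3.05, where static 3D replicate 1 is the only static array of chip 1.

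Among 11031 genes, limma called 1 as higher and 0 as lower in perfused 3D than in 2D, with 467 at an unadjusted p under 0.05. Camera with the preset correlation called 18 lists as higher and 4 as lower, a total that 2 of the 100 data sets simulated without an effect reached, and camera with an estimated correlation and fry called 0. With chip as a block 11 of the 22 passed, and 15 without both 2D replicate 1 and static 3D replicate 1. Genes without overlap between the groups made up 20.9%, where chance gives 20% if arrays were interchangeable. The smallest p-values of lower genes belonged to YAP1, a growth-control coactivator, not detected on the perfused arrays and at least 2.58-fold higher in 2D, and to CFAP36 at -1.12 (SE 0.25). VIM differed by -0.30 (SE 0.23), AFP by -0.78 (SE 0.32), CYP2E1 by 1.88 (SE 0.93) and COL1A1 by 1.65 (SE 1.97). Without 2D replicate 1 CYP2E1 was at 0.91, COL1A1 at -0.05 and VIM at -0.12, and without 2D replicate 2 COL1A1 was at 2.57.

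**Figure D3:**
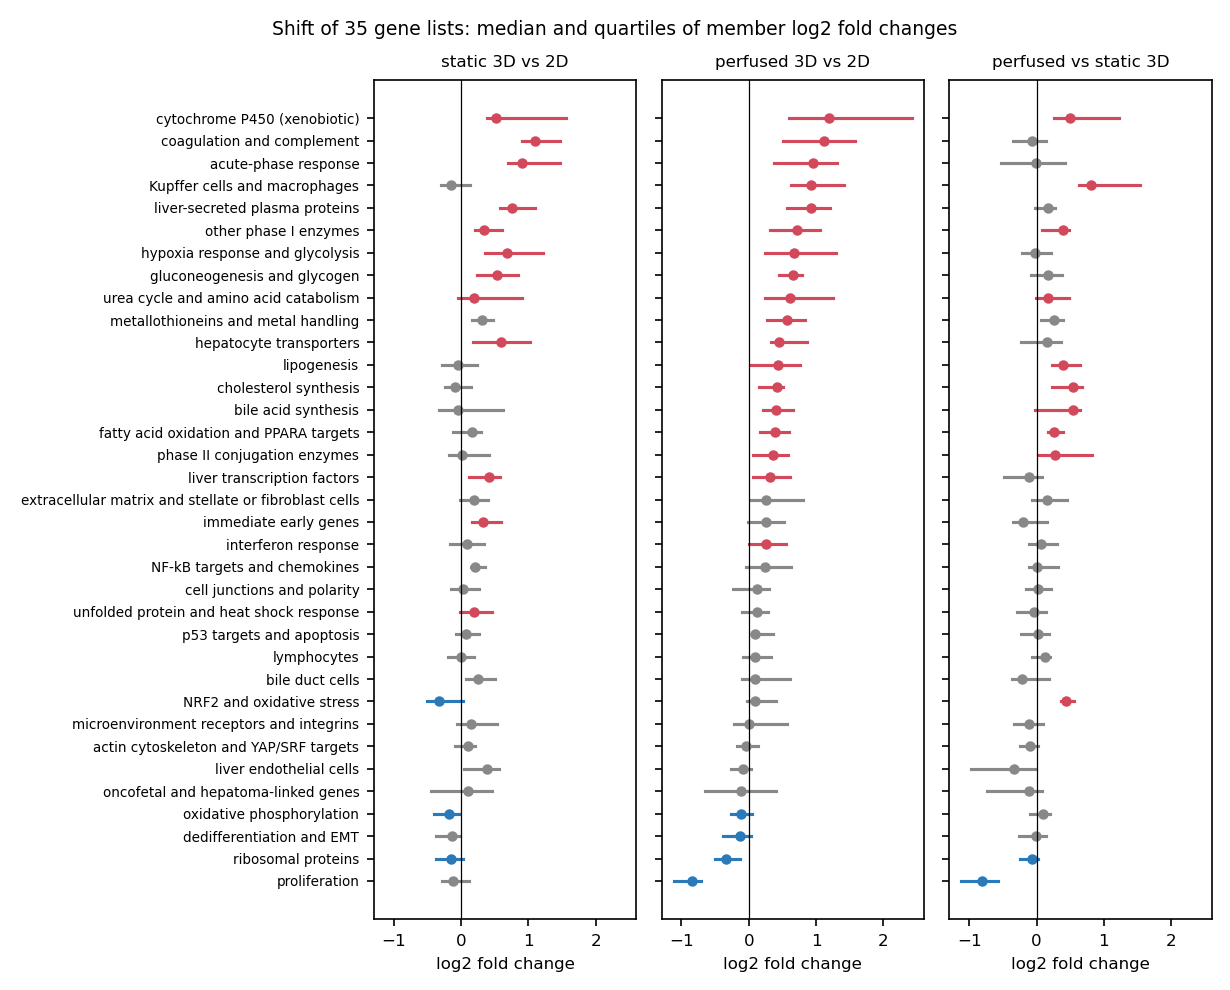
Median (points) and quartiles (lines) of the log2 fold changes of the members of 35 gene lists (rows) in the 3 comparisons (panels, horizontal axes in log2). Red and blue mark lists that passed camera with the preset correlation as higher or lower (12 and 3, 18 and 4, 10 and 2) and grey those that did not. With an estimated correlation 0 lists passed. The hypoxia list lies at 0.68 and 0.67 against 2D and at -0.03 between the 3D formats.

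Perfused 3D was compared with static 3D, which had the same seeded number and kind of scaffold. Static 3D replicate 1 stands apart and neither perfused array does. Flow and any difference in cell source or donor therefore cannot be told apart in the group means. CYP3A4 rose here too, by a log2 fold change of 3.63 (SE 0.24, limma adjusted p = 0.00223), at least 5.36-fold, with both perfused arrays above all 3 static arrays. As above, the SE and p-value include the spread of undetected values. The difference was 3.64 without 2D replicate 1 and static 3D replicate 1. Within chip 1, where 2 perfused arrays meet 1 static array, the difference was 3.42 (SE 0.31, adjusted p = 0.0915), and over the 22 alternatives that tested the gene the adjusted p ran from 3.3e-04 to 0.0915. CYP3A7 differed by 2.19 (SE 0.36) and POR by 1.25 (SE 0.31), neither past the test. The 15 P450 genes rose by a median of 0.50 (13 higher, 2 passing over the list alone), with an adjusted p = 0.735 with an estimated correlation, as for every list of this comparison that passed the preset test, and 44 of 100 simulated data sets gave a median as far from 0. The P450 median was 1.16 within chip 1, 0.32 without static 3D replicate 1, 0.79 without static 3D replicate 3 and 0.75 without perfused replicate 2, past the preset test each time. With probes detected on all 8 arrays alone, CYP3A4 not among them, the list did not pass (0.38). Every value within chip 1, here and below, rests on static 3D replicate 1, an array that stands apart. Its P450 mean was 9.95, against 10.5 and 10.8 on the other static arrays. The chip and that array cannot be told apart in such values.

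By the preset test alone, NRF2 and oxidative stress genes rose in perfused over static 3D by a median of 0.44 with 19 of 21 higher, among them the quinone reductase NQO1 at 0.95 (SE 0.30), the heme-degrading enzyme HMOX1 at 1.67 (SE 0.81) and TXN at 0.56 (SE 0.27). HMOX1 was at 1.10 without perfused replicate 2, and without static 3D replicate 1 TXN was at 0.32 and EHHADH, given below, at 0.50. Lipid lists rose as well, cholesterol synthesis by 0.53 (13 of 16, TM7SF2 at 1.19, SE 0.55), lipogenesis by 0.40 (17 of 21, FADS1 at 1.30, SE 0.44, and FADS2 at 1.22, SE 0.39) and fatty acid oxidation by 0.26 (25 of 29, EHHADH at 0.76, SE 0.35). Bile acid synthesis rose by 0.55 (9 of 13), other phase I enzymes by 0.39 (19 of 24), phase II enzymes by 0.27 (20 of 25, UGT1A1 at 0.85, SE 0.27) and urea cycle genes by 0.17 (26 of 35). Medians as far from 0 came up in 3 of 100 simulated data sets for bile acid synthesis, 8 for cholesterol synthesis, 9 for NRF2 genes, 16 for lipogenesis, 19 for other phase I and 23 for phase II enzymes, 31 for fatty acid oxidation and 52 for urea cycle genes. Within chip 1 the medians were 0.13 for NRF2 genes (adjusted p 0.0566), 0.19 for cholesterol synthesis, 0.37 for lipogenesis, 0.20 for bile acid synthesis and 0.01 for urea cycle genes, none past the preset test. They were 0.34 for fatty acid oxidation, 0.50 for other phase I and 0.43 for phase II enzymes, which passed. Without perfused replicate 2 the calls of NRF2 genes (0.09), cholesterol synthesis (0.20), lipogenesis (0.22), fatty acid oxidation (0.28), bile acid synthesis (0.24), phase I (0.28), phase II (0.11) and urea cycle genes (0.19) all ended. Without static 3D replicate 2 those of bile acid synthesis (0.29), cholesterol synthesis (0.32), phase I (0.24), phase II (0.20) and urea cycle genes (0.04) ended and the NRF2 median was 0.23. Without static 3D replicate 1 those of fatty acid oxidation (0.19), phase I (0.24) and phase II enzymes (0.24) ended and the urea cycle median was 0.27. Without perfused replicate 1 NRF2 genes moved to 0.72, cholesterol synthesis to 0.82 and urea cycle genes to 0.39. Median scaling, which raises the median of all genes by 0.12 here, gave 0.42 for fatty acid oxidation, 0.44 for phase II enzymes and 0.31 for urea cycle genes. Bile acid synthesis and urea cycle genes no longer passed with detection p under 0.01 on 3 arrays (0.51 and 0.15), nor bile acid synthesis with probes detected on all 8 (0.48). Urea cycle genes did not pass with the mean of all probes of a gene or chip as a random block (0.12 each), nor phase II enzymes with array weights (0.25). Without background correction phase I enzymes were at 0.20 and urea cycle genes at 0.10, without a filter phase II enzymes were at 0.10, and with the authors' values urea cycle genes were at 0.25, all still passing.

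By the preset test, proliferation genes fell in perfused against static 3D by a median of 0.82 (all 28 lower, PCNA at -1.32, SE 0.80). Macrophage genes rose by 0.81 (all 22 higher), and 51 and 49 of 100 simulated medians were as far from 0. The PCNA probe had a perfused mean of 6.64, below the lowest detected levels of 6.79 and 6.77 on those arrays. Another kept PCNA probe, detected on 6 arrays, differed by 0.21, the other way. Static 3D replicate 1 carried most of the proliferation shift: without it the medians of the 2 lists were -0.09 and 0.39 and neither list passed. The macrophage median was lower still, at 0.30, without perfused replicate 1. The proliferation median was -1.27 without static 3D replicate 2 and the macrophage median 1.51 without perfused replicate 2. Within chip 1, where static 3D replicate 1 is the only static array, these medians were -2.23 and 1.91. Ribosomal protein genes fell by a median of 0.07 (27 of 38 lower, 56 of 100 simulated medians as far from 0), which turned to 0.02 within chip 1 and to 0.07 with median scaling or with the authors' values. That call ended without static 3D replicate 2 (-0.06), static 3D replicate 3 (-0.12) or perfused replicate 1 (-0.02) and moved to -0.18 without static 3D replicate 1 and to -0.13 without perfused replicate 2. Hypoxia and glycolysis genes did not pass (median -0.03, mean 0.09, adjusted p 0.975), nor did plasma proteins (0.18, adjusted p 0.191, with APOA2 at 0.95, SE 0.32) or coagulation genes (-0.07, adjusted p 0.434). Limma called 1 gene as higher and 0 as lower, with 207 at an unadjusted p under 0.05, and camera with an estimated correlation and fry called 0 lists. Camera with the preset correlation called 10 lists as higher and 2 as lower, a total reached in 57 of the 100 data sets simulated without an effect. Within chip 1, 6 of the 12 passed, and 7 without both 2D replicate 1 and static 3D replicate 1. Genes without overlap made up 17.3%, against 20% by chance if arrays were interchangeable. Among uncalled genes the smallest p-values belonged to DCSTAMP, not detected in static 3D and at least 1.47-fold higher in perfused 3D, to YAP1, at least 2.05-fold higher in static 3D, and to CSRP2 at -1.07 (SE 0.27) and NKRF at -1.05 (SE 0.29).

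The 2 comparisons with 2D share its 3 arrays, so their fold changes correlate without any effect. The observed correlation across genes, which are not independent replicates, was 0.643. In data sets simulated without an effect the median was 0.504 (5th to 95th percentile -0.559 to 0.951). The covariance was 0.127 against a simulated median of 0.0545 (-0.107 to 0.385), and 70.7% of genes had the same sign against 66.1%. No gene could be called in both, because static 3D against 2D called 0 genes, so this overlap says nothing about agreement. The observed correlation and covariance lie inside the simulated ranges. Those ranges are wide and do not keep any donors shared between groups balanced. They therefore cannot decide whether the agreement exceeds what shared arrays give.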

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

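Chosen after the data were seen were the settings without both 2D replicate 1 and static 3D replicate 1, with a residual principal component, and with the unnamed probes. No paired analysis was run because the labels give no replicate numbers or donors per array, so the counts of calls come from models without donors. Among the static 3D arrays, 2D replicates 1, 2 and 3 each correlated most with that of their own number (0.921, 0.976 and 0.960). Whether these are pairs was not tested, and such likeness stays in the residual spread behind the counts. Over 29 alternatives, 4398 of 4442 values of named genes kept their direction and side of the threshold. Of the 188 named results only 2 were called in the main fit, so for the rest that side meant staying uncalled. Among the 188, 14 results, all uncalled, changed sign. Of 49 list results past camera's preset test 42 kept their sign and 13 passed in every alternative with a value. With an estimated correlation 0, 0 and 0 lists passed for static 3D against 2D, perfused 3D against 2D and perfused against static 3D, and with fry 0, 0 and 0. With an array left out the lists numbered 10 to 21, 16 to 22 and 5 to 14, and the genes 0 to 0, 0 to 1 (0 without perfused replicate 2) and 1 to 1. Perfused 3D against 2D and against static 3D gave 2 and 2 genes with no filter (20046 tested, 1 of each 2 not named here). CYP3A4, detected on 2 arrays, was not among those tested with detection p under 0.01 on 3 arrays (0 and 0 genes, 8791 tested) or on all 8 (0 and 0, 6408 tested). They were 0 and 0 with chip as a fixed block, and 0 and 0 with only the arrays of the 2 groups. Without 2D replicate 1 and static 3D replicate 1 the genes were 1 for static 3D against 2D and 2 for perfused 3D against 2D, 1 of them shared: HILPDA, chosen after its values were seen, at 3.95 (SE 0.30, adjusted p 0.0412). A residual component gave 1 gene for static 3D against 2D, which is optimistic since it comes from the same residuals. The correlation of the 2 comparisons with 2D was 0.492 without both arrays and 0.394 (without perfused replicate 1) to 0.801 (without 2D replicate 2) otherwise. Signs turned, the cause not tested, with median scaling (static 3D against 2D: unfolded protein response -0.0181; perfused against static: ribosomal proteins 0.0737), the authors' values (ribosomal proteins, perfused against static, 0.0652), chip as a block (perfused against 2D: cholesterol synthesis -0.0401, dedifferentiation 0.115; perfused against static: ribosomal proteins 0.0222) and without both arrays (static 3D against 2D: urea cycle -0.0553, ribosomal proteins 0.00886; perfused against 2D: phase II enzymes -0.00230). With an array left out, ribosomal proteins in static 3D against 2D ran from -0.243 to 0.0124 and phase II enzymes in perfused 3D against 2D from -0.00205 to 0.578. Median scaling moved the median of all genes by -0.13 for static 3D against 2D and 0.12 for perfused against static 3D. Genes near background, such as CYP3A4 outside perfusion, have only a bound for their fold.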

Other observations

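The tests of macrophage, proliferation, CYP3A4 and hypoxia patterns below were chosen after the results were seen, and the counts of other splits were planned. Among oncofetal genes, which fetal liver and hepatomas express, the imprinted RNA H19 lay at 8.30, 8.33 and 6.63 on the 2D arrays (not detected at 6.63), at 14.4, 10.8 and 11.6 on the static 3D arrays and at 10.99 and 8.45 on the perfused arrays, values looked up after they were seen. IGF2BP3, an RNA-binding protein of fetal tissue, was detected on 2D replicate 1 (8.41) and static 3D replicate 1 (7.46) alone, as was the imprinted gene PEG3 (7.13 and 8.01). The oncofetal list had medians of 0.10, -0.11 and -0.12 in static 3D against 2D, perfused 3D against 2D and perfused against static 3D, and 1 of its 10 genes passed in static 3D against 2D when adjusted over the list alone. AFP, the fetal albumin-like protein, was detected on all 8 arrays at 8.87 to 10.3.

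Cell structure and signalling lists did not pass in any comparison, with medians given here in the same order. Cell junctions had 0.03, 0.13 and 0.03, actin and YAP targets 0.10, -0.05 and -0.09, integrins and other microenvironment receptors 0.14, -0.00 (mean 0.23) and -0.11, NF-kB targets 0.20, 0.25 and 0.01, and p53 targets 0.07, 0.10 and 0.02. Among lists of other cells, matrix and stellate cells had 0.19, 0.26 and 0.16, liver endothelium 0.39, -0.08 and -0.33, bile duct 0.25, 0.09 and -0.21, and lymphocytes 0.01, 0.09 and 0.12. Bile acid synthesis in static 3D against 2D had a median of -0.04, a mean of 0.16 and a test direction up (adjusted p 0.368). Between the 3D formats, dedifferentiation genes had a median of -0.01 and a mean of 0.04, and NF-kB targets a mean of 0.14 with a test direction down. Red blood cell genes, with 2 of 12 measured, had means of 6.76 to 8.04 per array and were not tested as a list.

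Most macrophage genes and COL1A1 stand high on 6 arrays and are undetected on 2D replicate 1 and static 3D replicate 1, where proliferation genes are high. A pure HepG2 culture on every array is argued against by at least 18 of 22 macrophage genes being detected on each of the 6. Whether 2D replicate 1 and static 3D replicate 1 alone are HepG2 was not tested. All 10 measured oncofetal genes were detected on each of them, against 6 or 7 on the other arrays. The filter, however, also keeps genes detected on those 2 arrays alone. The chip is argued against by 7.02 on static 3D replicate 1 beside 8.92 or more on the other arrays of its chip, and weak hybridisation by 32.6% of probes detected there, against 29.7% on the lowest of the 6. Fewer other cells diluting the hepatocytes would raise hepatocyte genes as much as proliferation genes, but against the other arrays of their groups plasma protein genes differed by -1.25 and 0.17 on these arrays and proliferation genes by 2.57 and 2.20. A candidate explanation, not tested, is that these 2 arrays come from another cell source or donor than the rest, which labels with a donor per array would settle.

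CYP3A4 was detected on the perfused arrays alone. The chip stays open: the difference of 3.42 (SE 0.31, adjusted p 0.0915) within chip 1 exceeds 2 standard errors, but it rests on 1 undetected static array, with a spread taken from the other groups and a bound of 2.48. RNA of the paralogue CYP3A5 on the probe is argued against by its change of -0.0331 (SE 0.36). RNA of CYP3A7 on the probe cannot be told apart from CYP3A4 itself, because the bound of the CYP3A4 rise, 2.42 in log2, lies near the CYP3A7 change of 2.19. That flow raises CYP3A4 RNA is a hypothesis. A measurement specific to each paralogue, in cultures with the donor known, could test it.

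Hypoxia and glycolysis genes were higher in both 3D formats than in 2D. The chip is argued against by 0.71 within chips (adjusted p 2.8e-18), and the arrays 2D replicate 1 and static 3D replicate 1 by 0.69 without them (adjusted p 5.5e-20), both with camera's preset correlation, since with an estimated correlation the list did not pass (adjusted p 0.369 over both chips). The number of cells seeded cannot be told apart from the format, since it differs between 2D and both 3D formats, and the list's median between the 3D formats, seeded alike, was -0.0258 (adjusted p 0.975). Lower oxygen inside a scaffold may account for the rise, but so may cell number, and neither was measured here.

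Of the 10 ways to split the 6 arrays of 2D and static 3D into 3 and 3, all 10 gave 0 genes by limma, as the real split did (highest other 0, 519 genes at an unadjusted p under 0.05 in the real split), and 5 gave at least the real split's 15 lists (highest other 21). With 10 splits a share under 0.1 cannot be reached. The splits that keep 2D replicate 1 and static 3D replicate 1 on the same side gave 769 to 1509 genes at an unadjusted p under 0.05, and the splits that part them 91 to 814, so the ranges overlap.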
